A study of Homo sapiens with 4 samples.

How the data were processed

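The study holds 4 libraries from NCI-H441 cells infected with a lentivirus for rat Foxa2: 2 FOXA2 ChIP replicates and 2 input libraries. Chromatin was prepared with an enzymatic ChIP kit and the FOXA2 antibody is a commercial one, per the labels' protocols. The submitters' processing notes name hg38 as the build and Trim Galore 0.4.2, Bowtie2 2.3.3.1, SAMtools, Picard, MACS2 2.1.0 and bedtools as tools, with no role or settings. How duplicates and reads with several alignments were treated is not given in the sources used here. A single peak list was used per ChIP replicate, so peaks were called on each replicate separately; the input libraries had no file of their own here.

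The deposited lists give each peak's position and summit, a score, a fold enrichment (a ratio of the summit's pileup to its local background), and the −log10 of a p-value and of a q-value, all as the authors' peak caller made them. Fold enrichment and −log10 q were used to describe, rank and filter peaks. The deposited score was not used, as it is the −log10 p on another scale. The numbering of the peaks skips 39 numbers in replicate 1 and 41 in replicate 2, so some numbered peaks are not part of the lists used here.

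The deposited values allow the summit's pileup and background to be worked back. Fold enrichment was taken as the pileup plus 1 over the background plus 1, and the p-value as the upper tail of a Poisson distribution with that background. A whole pileup then gave the deposited −log10 p within 0.001 for 100% of the peaks of each replicate, with a largest error of 6.69e-05. The lowest background, the genome-wide floor, was 3.50 in replicate 1 and 1.54 in replicate 2. The narrowest peaks, 241 and 161 bp, were taken as the fragment length in each. Floor over fragment length is proportional to the number of tags, which gave the 1.52-fold ratio between the replicates; if the genome size setting was 2.7 Gb, there were 39.2 M and 25.8 M tags. Above the floor, 54.2% of the backgrounds of replicate 1 and 43.2% of those of replicate 2 were whole multiples, within 0.001, of a single factor, 0.990 and 0.953. With windows of 1 and 10 kb added, the factor accounted for 100% in each to 3 digits, of which the 10 kb step could by itself take 8.38% and 13.0% by chance. In MACS2 such steps arise from whole fragments of a separate control library scaled to the ChIP library, and the control libraries implied for the 2 replicates differed in tags by 1.46 times. Which control was paired with which replicate is not given in the sources used here. With lower pileups, replicate 2 needs a larger fold for the same p-value.

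Peaks on chromosomes 1 to 22 and X were analysed. A shared region is a run of peaks overlapping by at least 1 bp that holds peaks of both replicates, with its centre at the mean of the strongest summits, and its value is the mean ± SD over the 2 replicates. For random placement, peaks or regions were put anywhere on their own chromosome outside stretches of at least 1000 kb without a peak (100 seeded placements, 2658 Mb open). Genes came from a table for GRCh38.p14, the same assembly as hg38, with start and end but no strand, exons or sequence: 59098 genes of all kinds were used for location, and 19974 protein-coding genes for gene lists. The planned classes (near a 5′ end, exon, intron, between genes) were therefore replaced by the classes within 1 kb of either gene end, inside a gene and between genes. The planned gene list test (10 kb around 5′ ends, Fisher's exact test) was replaced by another test fixed beforehand, the gene plus 10 kb against 10000 random lists, each member drawn from the 200 genes closest to it in length. This was settled before any list result was seen. The planned searches for the forkhead motif, companion motifs, enriched short sequences and motif by strength need a genome sequence and were not run.

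Gene lists (25, of 20 genes each, by textbook knowledge) were fixed before the data were examined; 499 of 500 entries matched the table, and they name 483 different genes. The rule for named genes, also fixed before, takes from each list the 3 members with the highest mean fold enrichment of their strongest region and the first 2 in list order without a region, with the window changed as above, then the 10 strongest shared regions with their nearest protein-coding gene, and 15 genes of interest in any case. Some of the genes that the rule takes are not reported here. Shares carry 95% Wilson intervals, which cover counting error only. Permutation p-values are bounded by 100 placements (0.0099 one-sided, 0.0198 two-sided) and by 10000 lists (0.0002). Alternatives were a stricter threshold, other overlaps, other windows and backgrounds, other matching and each replicate left out.

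The scripts were tested on simulated data. Pileups were recovered for 100% of 2651 simulated peaks. For replicate overlap, 60% planted overlap came back as 61.0%, or 60.0% after chance. For location, 0 classes were called with no planted change, and a planted gene-end ratio of 1.73 came back as 1.67. For gene lists, with 19974 genes, 3.5% of 200 random lists had a p under 0.05, and lists with 80% or 95% of their genes bound were found in 96% and 100% of cases. Here regions were placed uniformly, the p was unadjusted and the lists with bound genes held only shorter genes. These shares need not hold for the real lists, which include long genes, real regions and adjusted p-values. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.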

Results

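Binding of the forkhead transcription factor FOXA2 across the genome was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in NCI-H441 cells, a human line from a papillary adenocarcinoma of the lung that is widely used as a model of the distal airway epithelium. The cells had been infected with a lentivirus carrying the rat Foxa2 gene. There were 2 ChIP replicates with an antibody to FOXA2 and 2 input libraries of chromatin sequenced without antibody. Each ChIP replicate came with its own list of peaks on hg38, and the input libraries enter only through the background of those peaks. Nothing in the labels says that the replicates came from separate cultures, so their spread may be technical. No cells without the Foxa2 virus are part of the design, so the peaks describe where the FOXA2 antibody enriched chromatin and not what the added factor changed. Rat FOXA2 from the virus cannot be told apart here from any FOXA2 of the cells themselves. The question was where in the genome FOXA2 binds and at which genes.

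FOXA2 peaks were numerous in both replicates, with 91885 in replicate 1 and 89181 in replicate 2. The median peak was 440 bp wide in replicate 1 and 246 bp in replicate 2, and the peaks covered 49.5 and 27.0 Mb of the genome. Fold enrichment, the authors' value for each peak, had a median of 3.33 in replicate 1 and 3.60 in replicate 2 and reached 23.3 and 31.9. The pileup of fragments at the summit, worked back from the deposited values, had a median of 23 in replicate 1 and 12 in replicate 2. Replicate 1 was the deeper library, with 1.52 times as many tags as replicate 2 by the ratio of the genome-wide backgrounds after each was divided by a fragment length taken from the narrowest peaks (241 and 161 bp). The lists reached down to a −log10 p of 2.00 in each replicate, and 8.07% of the peaks of replicate 1 and 20.7% of those of replicate 2 had a q-value above 0.05. At a −log10 q of at least 10 there were 26834 and 16740 peaks.

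The background against which the peaks stand was uneven along the genome, and it was uneven in the same places in both replicates. The highest of 542 bins of 5 Mb was at 35 to 40 Mb of chromosome 14, the bin that holds NKX2-1 and FOXA1, lineage transcription factors of the lung. There the median background at peaks was 3.30 times the genome-wide floor in replicate 1 and 3.09 times in replicate 2. Bins on chromosome 7 at 115 to 120 Mb (3.11 and 2.98 times) and on chromosome 11 at 75 to 80 Mb (3.11 and 2.79 times) followed. At the other end, 16 bins lay at the floor, within 0.001 of it as a ratio, in both replicates, among them 10 to 30 Mb of chromosome 9 and several bins of the X chromosome. Across bins, the values of the replicates had a Spearman's rho of 0.939. Fold enrichment is a ratio to this background, whereas the number of peaks called also depends on the fragments a region yields.

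**Figure D1:**
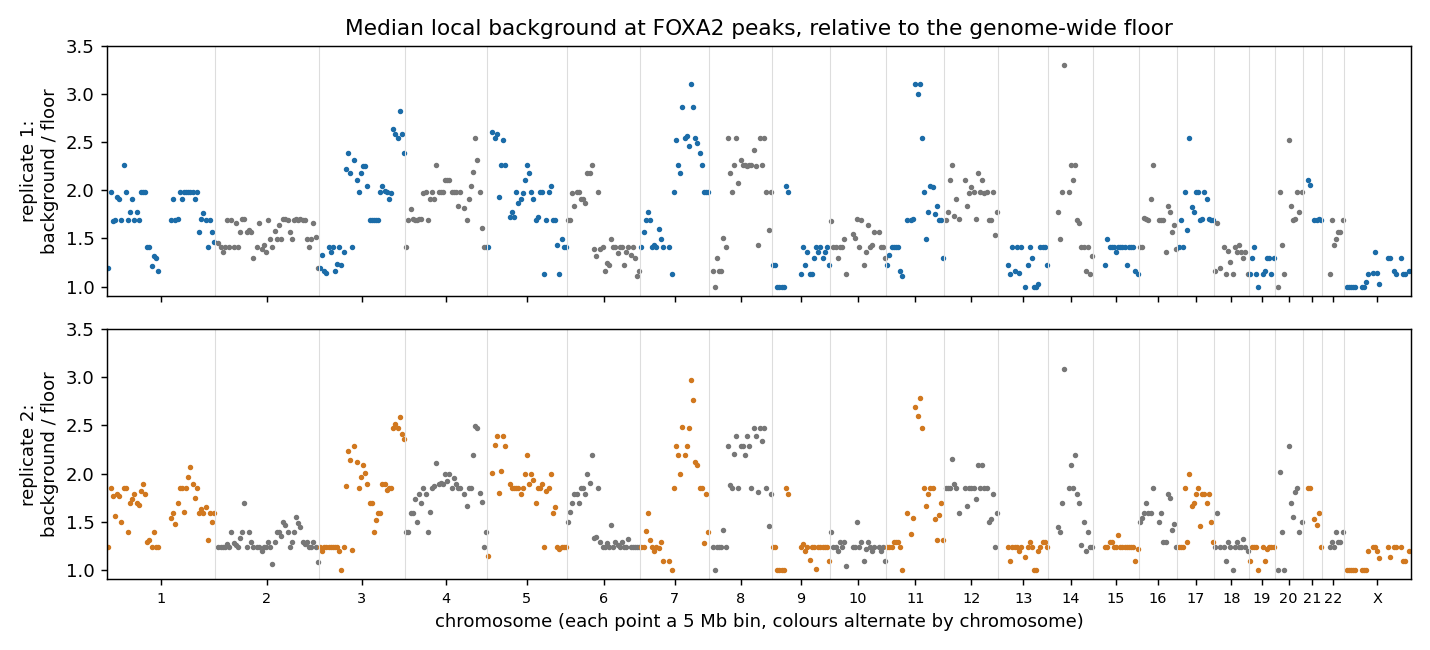
Median local background at FOXA2 peaks in bins of 5 Mb along chromosomes 1 to 22 and X, divided by the genome-wide floor of that replicate, for replicate 1 (top) and replicate 2 (bottom). Each point is a bin, and the bin on chromosome 14 that holds NKX2-1 and FOXA1 is the highest in both panels, at 3.30 and 3.09.

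The replicates shared most of their strong peaks and a minority of their weak ones. Of the replicate 1 peaks on chromosomes 1 to 22 and X, 53.9% (49520 of 91878, 95% Wilson interval 53.6 to 54.2%) overlapped a replicate 2 peak by at least 1 bp, and 61.2% of replicate 2 peaks (54539 of 89174, 60.8 to 61.5%) overlapped a replicate 1 peak. With the peaks of the other replicate placed at random on their chromosomes, the shares were 2.87% and 2.97%, so the overlap was 18.8 and 20.6 times that of random placement (one-sided permutation p = 0.0099 each, the smallest that 100 placements can give). Moving them by 20 to 200 kb instead, a comparison chosen after seeing the data, gave shares of 4.30% and 4.44%. The overlap was 12.5 and 13.8 times these. Overlap rose with strength, from 16.6% of replicate 1 peaks at a −log10 q under 1.3 to 90.3% between 10 and 20, and all 2361 peaks at 50 or more overlapped. Over the same classes the shares of replicate 2 rose from 26.2% to 99.4%, and all 796 peaks at 50 or more overlapped.

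**Figure D2:**
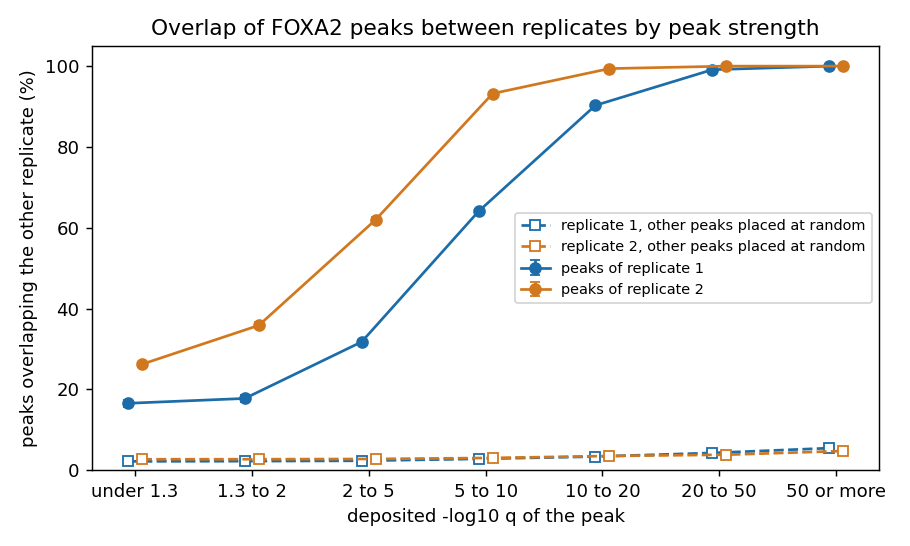
Share of FOXA2 peaks that overlap a peak of the other replicate by at least 1 bp (vertical axis, percent) by the peak's deposited −log10 q (horizontal axis). Filled circles are the observed shares with 95% Wilson intervals, mostly smaller than the circles, and open squares the shares with the other replicate's peaks placed at random; the observed shares rise from 16.6% and 26.2% to 100%, while the random ones stay at or below 5.47%.

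Overlapping peaks of both replicates formed 49125 shared regions, which had a median width of 612 bp and covered 35.2 Mb. The summits of the replicates lay a median of 54 bp apart and within 100 bp of each other in 76.6% of the shared regions. Across regions, log2 fold enrichment had a Spearman's rho of 0.614 between the replicates (bootstrap 95% interval 0.609 to 0.620) and a Pearson's r of 0.638; regions are not independent replicates, so no p is given. Fold enrichment tended to be lower in replicate 1, with a median log2 ratio to replicate 2 of −0.19 and an SD of 0.57 across regions. Both peaks of a region had a q-value under 0.05 in 90.9% of the shared regions. Peaks without a partner were weaker, with a median fold enrichment of 2.83 in replicate 1 and 3.08 in replicate 2, against 4.34 and 4.55 for those with one.

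The strongest shared region of the genome lay between genes on chromosome 4 (137613752 to 137615395), 82219 bp from PCDH18, a protocadherin gene. Its fold enrichment was 24.5 ± 2.46 (SD, n = 2). Of the 10 strongest shared regions, 7 lay inside genes of any kind and 3 between genes, and none lay within 1 kb of a gene end. Those inside a protein-coding gene were in EARS2, a mitochondrial glutamyl-tRNA synthetase gene (chromosome 16, 23540125 to 23540944, 22.7 ± 0.927), in DIS3L2, an exoribonuclease gene (chromosome 2, 232300619 to 232301963, 20.4 ± 3.78), and in GAPVD1 (chromosome 9, 125296656 to 125297964, 20.3 ± 2.44). The other 6 had NEUROD6, UBE2V2, BBOX1, IKZF2, KCTD6 and C1QTNF3 as their nearest protein-coding genes, at 1385 to 67815 bp, with mean fold enrichments of 19.99 to 23.2. The region near NEUROD6 had unequal replicates, with a fold enrichment of 14.5 in replicate 1 and 31.9 in replicate 2.

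FOXA2 regions favoured genes and their ends, by small ratios. Of the shared regions, 8.67% had their centre within 1 kb of either end of an annotated gene (95% Wilson interval 8.42 to 8.92%), against 6.55% of regions placed at random on the same chromosomes, a ratio of 1.32. A further 59.4% lay inside a gene, against 55.6% at random (1.07 times), and 31.9% lay between genes, against 37.8% (0.844 times). Each share lay outside the range of the 100 random placements (two-sided permutation, adjusted p = 0.0198 each, the smallest they can give). The share at gene ends was lower among strong regions. It was 9.46% in the tenth of the shared regions with the lowest mean fold enrichment and 6.90% in the tenth with the highest (odds ratio 0.709, two-sided Fisher's exact p = 4.05e-06, with regions treated as independent). The log2 ratio at gene ends was 0.40 for shared regions, 0.22 for the peaks of replicate 2 alone, without replicate 1, and 0.60 for those of replicate 1 alone, without replicate 2. With regions moved by 20 to 200 kb in place of anywhere on the chromosome, a comparison chosen after seeing the data, the log2 ratio inside genes was 0.01 in place of 0.10 and that between genes −0.10 in place of −0.24.

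Peaks found in a single replicate differed in where they lay. Of the 42358 peaks found in replicate 1 only, 11.4% had their summit within 1 kb of a gene end (95% Wilson interval 11.1 to 11.7%), and of the 34635 found in replicate 2 only, 5.76% did (5.52 to 6.01%). The odds ratio was 2.11 (two-sided Fisher's exact p = 3.95e-173, with peaks treated as independent). The share for peaks found in replicate 2 only lay below the 6.55% of shared regions placed at random. Among peaks found in replicate 1 only, the share rose with strength from 10.5% at a −log10 q below 2 to 14.8% at 10 or more, where there were 1398 peaks. Shared peaks lay in between, at 8.65% in replicate 1 and 8.57% in replicate 2.

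**Figure D3:**
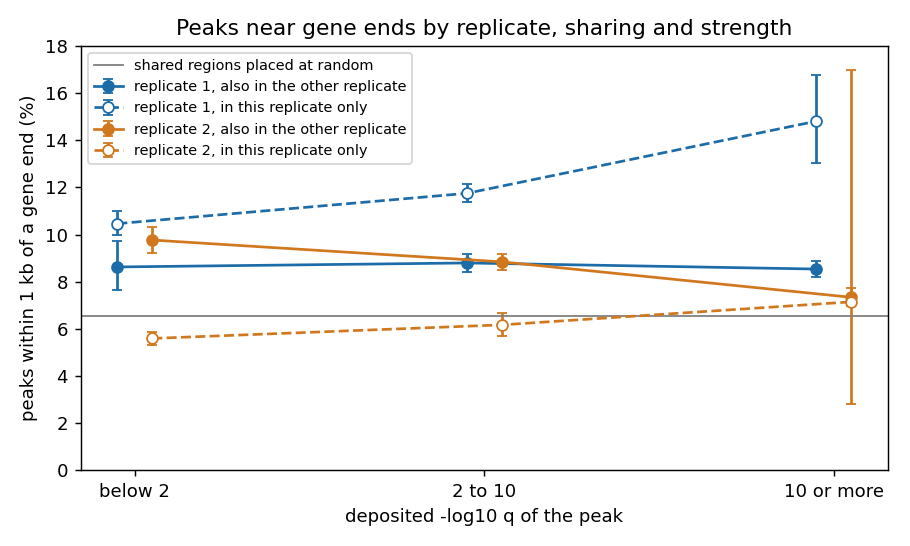
Share of FOXA2 peaks whose summit lies within 1 kb of either end of an annotated gene (vertical axis, percent) by the peak's deposited −log10 q (horizontal axis), for peaks of each replicate that overlap the other replicate or do not. Bars are 95% Wilson intervals and the grey line is the share of shared regions placed at random, 6.55%; peaks found in replicate 1 only rise from 10.5% to 14.8%, and those found in replicate 2 only lie between 5.59% and 7.14%, the last from 56 peaks.

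At the level of genes, FOXA2 regions were more frequent than expected at genes of the alveolar type II cell, at transcription factors of the foregut and lung, at junction genes of the epithelium, at genes of EGF signalling and MAP kinase feedback, at targets of TEAD and YAP, and at stress and inflammatory genes. They were less frequent at olfactory receptor genes. Of 19974 protein-coding genes, 10082 (50.5%) had the centre of a shared region within the gene or 10 kb of it. Because long genes catch more regions, each of 25 lists fixed before the data were examined was set against 10000 random lists matched on gene length (two-sided permutation test, Benjamini-Hochberg over the 25 lists). Each random gene was drawn on its own, whereas some list members stand side by side, so the p-values of such lists may be too small. By this test 7 lists held more genes with a region than the random lists and 1 held fewer. With the peaks of replicate 2 alone none of these calls held. With those of replicate 1 alone the alveolar type II, foregut, junction and inflammatory lists were not called. Over 12 alternatives each of the 8 lists was called in 5 to 9. Among the strongest 10000 shared regions the alveolar type II, stress and inflammatory lists were close to their random lists.

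Of the 20 genes of surfactant and the alveolar type II cell, which makes surfactant in the distal lung, 16 had a region against 9.21 expected (adjusted permutation p = 0.016). ETV5, an ETS transcription factor of that cell, had its strongest region 155 bp from the gene (chromosome 3, 186109029 to 186109677) with a fold enrichment of 13.3 ± 0.949 (SD, n = 2). The regions beside the surfactant protein genes SFTPA1 (chromosome 10, 79610608 to 79611347, 10.6 ± 1.13) and SFTPA2 (79560154 to 79560808, 10.6 ± 1.65) lay 115 and 118 bp from the genes. SFTPA1 and SFTPA2 are near-identical copies, and reads may be divided between them. SFTPB had 2 regions, the strongest inside the gene, 418 bp from an end, with 6.47 ± 1.55. SFTPD had 3, the strongest at 5374 bp with 5.77 ± 0.307 and the nearest at 2.661 kb. SFTPC, the marker gene of the type II cell, and the lipid transporter gene ABCA3 had none.

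Among foregut and lung transcription factors 16 of 20 had a region against 10.3 expected (adjusted permutation p = 0.0258). Strong regions lay in FOXP1 (chromosome 3, 71030519 to 71032119, 11.96 ± 1.45) and in TP63 (11.4 ± 2.91). FOXP1 held 50 shared regions and TP63 held 31, counts that are not adjusted for gene length or background. Background was 2.18 and 2.14 times the floor in the bin of FOXP1 and 2.83 and 2.59 times in that of TP63. FOXA1, the closest relative of FOXA2, had 4 regions, the strongest 718 bp from the gene (chromosome 14, 37588189 to 37589913, 7.92 ± 0.559). NKX2-1, the thyroid transcription factor that marks lung epithelium, had 5, the strongest inside the gene (chromosome 14, 36519322 to 36520294, 5.12 ± 1.97). Both lie in the bin with the highest background. FOXA3 had 1 region, at 4632 bp, with 4.34 ± 0.835. The FOXA2 gene itself had no peak in either replicate within the gene or 10 kb of it, and its nearest shared region was 131.7 kb away.

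Epithelial junction and adhesion genes had a region in 16 of 20 cases against 10.4 expected (adjusted permutation p = 0.0356), led by the desmoplakin gene DSP (13.2 ± 6.17), the splicing regulator gene ESRP1 (12.1 ± 6.61) and the E-cadherin gene CDH1, which held 8 regions (strongest on chromosome 16, 68755311 to 68756674, 10.9 ± 5.60). All 3 had lower fold enrichment in replicate 1 than in replicate 2. EPCAM and CLDN3 had none. Genes of EGF signalling and MAP kinase feedback had a region in 16 of 20 cases against 9.24 (adjusted permutation p = 0.016), with the receptor gene ERBB2 at 11.8 ± 4.18 and the ligand gene AREG at 11.2 ± 3.99 after ETV5, which is on this list too. HBEGF and SPRY4 had none. Targets of TEAD factors and YAP had a region in 18 of 20 cases against 11.6 (adjusted permutation p = 0.0117), with AMOTL1 at 12.1 ± 1.48, PTPN14 at 11.8 ± 3.36 and CRIM1 at 10.8 ± 0.0742, and none at F3 or GADD45B.

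AP-1 and stress response genes had a region in 14 of 20 cases against 6.65 expected (adjusted permutation p = 0.0117), led by IER3 (13.1 ± 4.40) and the chaperone gene DNAJB1 (8.62 ± 5.06), and none at JUND or EGR1. Inflammatory cytokine and chemokine genes had one in 14 of 20 cases against 6.27 (adjusted permutation p = 0.01), led by the neutrophil chemokine gene CXCL8 (chromosome 4, 73740270 to 73741805, 13.1 ± 7.25), whose fold enrichment was 7.93 in replicate 1 and 18.2 in replicate 2, and by IL18 (9.826 ± 0.4003) and CCL20 (6.50 ± 4.91). CCL2 and CCL5 had none. Olfactory receptor genes, which are expressed mainly in the nose, had a region in 1 of 20 cases against 6.24 (adjusted permutation p = 0.0356), at OR11A1 with 3.05 ± 0.822.

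These calls depended on which peaks were counted, on the window and on the test. Peaks of replicate 2 alone, without replicate 1, called none of the 25 lists (7 were higher at an unadjusted p under 0.05), and peaks of replicate 1 alone, without replicate 2, called 3 lists higher and 2 lower (6 and 2 at an unadjusted p under 0.05). The 3 higher were the EGF, AP-1 and TEAD lists, and the 2 lower the olfactory receptor and muscle lists. The surfactant, foregut, junction and inflammatory lists were called with neither replicate alone. Regions with a −log10 q of at least 10 in each replicate called 2 lists higher, the foregut and lung transcription factors and the EGF list, and none lower, with 8 higher and 0 lower at an unadjusted p under 0.05. In that set the surfactant list, with 9 of 20 against 4.19 expected, and the liver list, with 9 against 3.84, had the same adjusted permutation p of 0.0957, as did the junction list (10 against 5.34) and the AP-1 list (7 against 2.76). The TEAD list (11 against 7.03, adjusted permutation p = 0.177) and the inflammatory list (5 against 2.32, adjusted permutation p = 0.268) did not pass there either. With the strongest 10000 shared regions the foregut and lung transcription factors (13 of 20 against 4.93, adjusted permutation p = 0.005) and the alveolar type I list were called. Of the other lists called higher with all shared regions, the junction (9 against 4.19), EGF (8 against 3.63) and TEAD (10 against 5.82) lists had an adjusted permutation p of 0.123 to 0.132. The surfactant (5 against 3.19, adjusted permutation p = 0.668), AP-1 (3 against 2.05, adjusted permutation p = 0.983) and inflammatory lists (2 against 1.69, adjusted permutation p = 1) were close to their random lists. At a q-value under 0.05 in each replicate, chosen after seeing the data, the AP-1 list (11 against 6.31, adjusted permutation p = 0.119) and the olfactory receptor list (1 against 5.83, adjusted permutation p = 0.0614) did not pass.

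With a window of 2 kb around either gene end and Fisher's exact test, the surfactant list (6 of 20 against 3.20, adjusted p = 0.327 by this exact test) and the olfactory receptor list (1 against 3.21, adjusted p = 0.487 by this exact test) were not called, and the other 6 were. With 50 kb, of the 8 lists only the TEAD list (20 of 20 against 14.9, adjusted exact p = 0.0481) and the olfactory receptor list (5 against 14.9, adjusted exact p = 0.000132) were called. The same test was also applied, after seeing the data, to 10 kb around either gene end, where the foregut and inflammatory lists (13 of 20 against 8.15 each, adjusted exact p = 0.0959) were not called, and to the gene plus 10 kb without matching on length, where the AP-1 and inflammatory lists (14 of 20 against 10.1 each, adjusted exact p = 0.222) were not. Matching on gene density or control background as well as length, or taking overlapping members as 1 locus, kept all 8 calls. The last 2 of these alternatives were chosen after seeing the data. A joined locus counted when any member had a region, while its random genes were matched on the length of 1 member. Where members were joined the expected number is therefore too low, so this alternative cannot back the lists called higher.

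**Figure D4:**
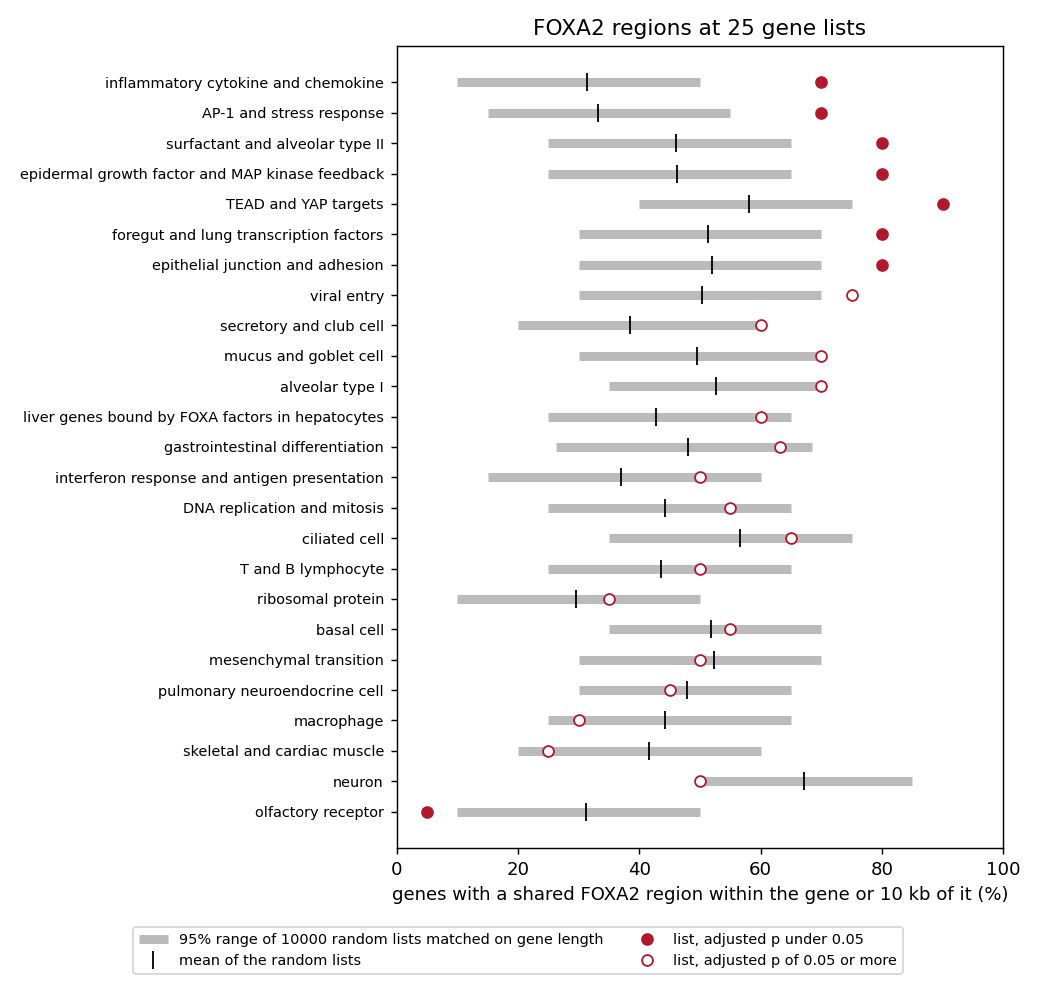
Share of the genes of each of 25 lists that have the centre of a shared FOXA2 region within the gene or 10 kb of it (circles, percent). Grey bars are the 95% range and ticks the mean of 10000 random lists matched on gene length; filled circles mark the 8 lists with an adjusted p under 0.05, of which the olfactory receptor list, at 5.0%, lies below its random range.

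The other lists did not pass. Genes for viral entry had a region in 15 of 20 cases against 10.1 expected (adjusted permutation p = 0.0939), with NRP1 (11.7 ± 4.68) and the protease gene FURIN (10.8 ± 0.844) ahead. Matched on control background as well, a comparison chosen after seeing the data, this list was called higher (adjusted permutation p = 0.0381). Secretory and club cell genes had 12 of 20 against 7.69 (adjusted permutation p = 0.163); CLDN10 had 14.99 ± 1.56 and KRT7 9.80 ± 2.56, while SCGB1A1, the marker gene of the club cell, had no peak in either replicate and SCGB3A2 had a single peak, in replicate 2. Mucus and goblet cell genes had 14 of 20 against 9.90 (adjusted permutation p = 0.214). There the transcription factor gene CREB3L1 led with 13.9 ± 0.646, followed by MUC20 with 11.1 ± 1.60 and by SPDEF, a driver of goblet cell differentiation, with 10.7 ± 3.16. The airway mucin genes MUC5AC (10.5 ± 2.67) and MUC5B (5.16 ± 2.44) each had 1 region outside the gene, at 6897 and 3061 bp. Alveolar type I genes had 14 of 20 against 10.5 (adjusted permutation p = 0.272), with some of the highest values among the named genes: 18.6 ± 9.52 near SPOCK2, 16.1 ± 1.67 in CLIC5 and 13.1 ± 2.65 near EMP2. With the strongest 10000 shared regions this list was called higher, with 10 of 20 against 4.34 (adjusted permutation p = 0.04).

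Genes of other organs that express FOXA factors did not pass either. Liver genes had a region in 12 of 20 cases against 8.56 expected (adjusted permutation p = 0.272), with the transferrin gene TF at 14.04 ± 1.84, TAT at 11.4 ± 2.41 and HNF4A at 9.89 ± 7.07, where the replicates gave 4.89 and 14.9. TTR and APOA1 had none. In the stricter sets the liver list stood higher relative to its random lists without passing, with 9 of 20 against 3.84 at a −log10 q of at least 10 (unadjusted permutation p = 0.0134, adjusted p = 0.0957) and 7 against 2.87 among the strongest 10000 (unadjusted permutation p = 0.0272, adjusted p = 0.128). Gastrointestinal genes had 12 of 19 against 9.13 (adjusted permutation p = 0.366), with LGALS4 at 12.4 ± 1.99 and HNF4G at 10.8 ± 1.41. Ciliated cell genes (13 of 20 against 11.3, adjusted permutation p = 0.69), basal cell genes (11 against 10.4, adjusted permutation p = 0.999) and pulmonary neuroendocrine genes (9 against 9.59, adjusted permutation p = 0.999) were close to their random lists, and the basal keratin genes KRT5 and KRT14 had no region. Mesenchymal transition genes had 10 of 20 against 10.5 (adjusted permutation p = 1), with FN1 at 8.71 ± 1.32 and none at VIM or CDH2.

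Interferon and antigen presentation genes had 10 of 20 against 7.40 expected (adjusted permutation p = 0.436), with IRF1 at 12.1 ± 0.736. Replication and mitosis genes had 11 against 8.84 (adjusted permutation p = 0.592), and ribosomal protein genes 7 against 5.91 (adjusted permutation p = 0.859). The lists of cell types foreign to the line did not pass with shared regions. Of these, skeletal and cardiac muscle had 5 of 20 against 8.31 (adjusted permutation p = 0.272), but with the peaks of replicate 1 alone, without replicate 2, it was called lower, with 5 against 11.9 (adjusted permutation p = 0.015). Neurons had 10 against 13.4 (adjusted permutation p = 0.272), T and B lymphocytes 10 against 8.73 (adjusted permutation p = 0.856) and macrophages 6 against 8.85 (adjusted permutation p = 0.381). Single genes on these lists were still among the stronger ones, such as the lymphocyte genes PAX5 (12.7 ± 6.49) and CD3E (12.2 ± 1.12) and the macrophage receptor gene MRC1 (12.8 ± 0.752).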

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

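Outside chromosomes 1 to 22 and X, which the comparisons use, unplaced or unlocalised contigs held 5 peaks in replicate 1 and 7 in replicate 2, which is more than the 3 that a count of 0 allows. That limit is the only reason they are named, and it says nothing of how many peaks such contigs would hold by chance, which was not computed. They stood on 4 and 5 contigs, of which 2 held peaks in both replicates, had fold enrichments of 2.57 to 3.999 and 2.26 to 4.72, and 1 of those of replicate 1 overlapped a peak of replicate 2.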

How the results depend on the processing

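Alternatives chosen after seeing the data were the limit of q under 0.05, moves of 20 to 200 kb, Fisher's exact test with the gene plus 10 kb or 10 kb of either gene end, overlapping list members as 1 locus, matching on control background, and the strongest 10000 regions for location. Replicate overlap stayed above random placement under each of 6 alternatives, from 28.4% (50% of both peaks) to 70.2% (strongest 10000) of replicate 1 and from 29.2% to 90.3% (−log10 q of at least 10) of replicate 2. Each location class kept its direction and its call under 7 alternatives, replicates left out included; log2 ratios at gene ends ran from 0.19 to 0.60. At a −log10 q of at least 10, peaks numbered 26834 and 16740, rho across regions was 0.421, and 2 lists were higher and 0 lower. Ranked by −log10 q, rho was 0.725. With 50 kb of either gene end 1 list was higher, with 2 kb 0 were lower, at q under 0.05 0 were lower, and with the strongest 10000 regions 2 were higher and 0 lower. With a replicate left out, 0 to 3 lists were higher and 0 to 2 lower; the share of genes with a region was then 59.4% (replicate 2 alone) or 66.5%, against 50.5%, and 26.0% at the stricter threshold. Stricter sets hold fewer regions by construction; otherwise the cause was not tested. Of 12 alternatives, the EGF and TEAD lists were called in 9, foregut factors in 8, junction and olfactory receptor genes in 7, surfactant and AP-1 genes in 6 and inflammatory genes in 5. Overlapping members as 1 locus is among the 12 and favours calls of higher. Calls gained were alveolar type I genes higher with the strongest 10000 regions, viral entry genes higher with matching on control background, and muscle genes lower without replicate 2. Of 77 named genes with a region, 69 had one at the stricter threshold. Motif alternatives were not run, as no genome sequence was used here. No paired analysis was possible because the input libraries have no file here. The median pileup was 12 in replicate 2 and 23 in replicate 1; replicate 1 had more tags and longer fragments, and their parts in this were not separated.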

Other observations

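In this part the tests of families, clusters and 5′ ends, of strong against weak gene-end peaks, of fold ratios at gene ends and of bins between the replicates were chosen after the results were seen. Gene families, taken as protein-coding genes whose symbols share the letters before the first digit (146 families of at least 15 members, leaving out the olfactory receptors, which had a list of their own, and genes with placeholder LOC symbols), were set against random lists matched on gene length. Keratin genes (KRT), which build the filaments of epithelial cells, had a shared FOXA2 region at 29 of 55 members against 17.4 expected (adjusted permutation p = 0.0487 over 146 families), the only one of these families called higher. Families called lower were the zinc finger genes ZNF (178 of 517 against 256.6, adjusted permutation p = 0.00973), the beta-defensins DEFB (0 of 39 against 10.9, adjusted permutation p = 0.00973), GOLGA (4 of 36 against 15.3, adjusted permutation p = 0.00973), PRAMEF (0 of 23 against 6.46, adjusted permutation p = 0.0487) and SPDYE (1 of 19 against 7.54, adjusted permutation p = 0.0487). Members of a family often stand side by side, so these p-values are too small. With overlapping windows taken as 1 locus, which counts when any member had a region, and all 146 families tested again, only GOLGA passed (4 of 35 against 14.9, adjusted permutation p = 0.0292). DEFB had 0 of 24 against 6.81 and KRT 13 of 18 against 5.82 (adjusted permutation p = 0.0584 each), ZNF 146 of 334 against 172.1 (adjusted permutation p = 0.146), SPDYE 1 of 13 against 5.11 (adjusted permutation p = 0.476) and PRAMEF 0 of 9 against 2.45 (adjusted permutation p = 0.725). Each joined locus was set against single random genes matched on the length of 1 of its members. Its expected number is therefore too low, which favours an excess, as for KRT, and works against a deficit. Members of GOLGA, PRAMEF and SPDYE have close copies in the genome, where short reads align to several places.

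Shared regions also came in clusters. With centres at most 20 kb apart joined, 280 clusters held at least 10 regions, against a mean of 1.35 and at most 5 in 100 random placements on the same chromosomes, where the largest cluster held 13. Those placements did not follow the background, with which region counts rise over bins (rho 0.559). The comparison therefore does not separate clustering from uneven background. The largest observed held 33 regions over 201 kb on chromosome 3 (102057966 to 102258697), 126 kb from ZPLD1, followed by 32 within ATXN1 (chromosome 6, 16636049 to 16771175). A cluster of 31 regions lay on chromosome 8 (128152194 to 128344319), 409 kb from its nearest protein-coding gene, the oncogene MYC, and 1 of 30 regions on chromosome 4 (74533892 to 74670728), 74.0 kb from BTC, which encodes an EGF receptor ligand. Clusters of 26 regions each lay at PRKCH, at FOXP1 and at AGR3, a gene of the secretory pathway (chromosome 7, 16876733 to 17042696, highest mean fold enrichment 17.4). Background in the bin of the cluster nearest MYC was 2.54 and 2.47 times the floor, and nearest ZPLD1 2.25 and 2.09 times. The medians of all bins were 1.70 and 1.39, while large clusters nearest SERP2 and MREG lay at 1.41 and 1.24. Membership depends on the joining distance: at 10 kb there were 55 clusters of at least 10 regions, against 0 in each placement, and the first was 15 regions at SH3RF1 (chromosome 4, 169225358 to 169288382). Around the FOXA2 gene, within 100 kb, replicate 1 had 1 peak and replicate 2 had 0, with no shared region, against 16 shared regions within 100 kb of FOXA1 and 24 around NKX2-1. The background differs between these places, at 1.13 and 1.0 times the floor in the bin of FOXA2 and 3.30 and 3.09 times in that of FOXA1 and NKX2-1, and region counts rise with background, so these counts are not on an equal footing.

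The gene table lacks strand, but 534 protein-coding genes of at least 5 kb have a divergent transcript named after them, which marks their 5′ end. They are a selected set, and their shares need not hold for other genes. Within 1 kb of that end, 9.0% of these genes had a shared region, against 3.93% at the 3′ end (48 against 21 genes, exact binomial test on discordant genes, adjusted p = 0.00218 over 4 sets). Among the strongest 10000 shared regions the difference did not pass, with 9 genes at the 5′ and 6 at the 3′ end (same exact test, adjusted p = 0.81). Peaks found in replicate 1 only lay at 95 of the 5′ ends and 24 of the 3′ ends (17.8% against 4.49%, same exact test, adjusted p = 1.24e-11), and peaks found in replicate 2 only at 16 and 18 (2.996% against 3.37%, adjusted p = 0.864).

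The excess of gene ends among peaks found in replicate 1 only, 11.4% against 5.76% for replicate 2, was weighed against 3 technical explanations, and no biological one was tested, as the design gives no group that separates the replicates. Weaker sites reached by the deeper library are argued against as the whole cause, since among these peaks the share at gene ends rose with strength, from 10.5% at a −log10 q below 2 to 11.7% at 2 to 10 and 14.8% at 10 or more (only 1398 peaks), the last higher than the first by 4.35 percentage points (95% bootstrap interval 2.45 to 6.31). They may still contribute, as the share fell with strength among shared peaks of replicate 2, from 9.77% to 7.34% over the same classes, and among shared regions from 9.46% in the weakest 10% to 6.90% in the strongest. Shared peaks of replicate 1 showed no such fall, with 8.62%, 8.79% and 8.54%. For peaks found in replicate 2 only the share went from 5.59% to 7.14%, the last from 56 peaks. A tilt of the whole of replicate 1 towards gene ends may contribute: at shared regions the median log2 ratio of replicate 1 to replicate 2 was higher by 0.0567 (0.0347 to 0.0808) at gene ends than elsewhere. For open chromatin that is also enriched in the control, the prediction set beforehand was a higher median relative background at gene-end peaks, beyond its bootstrap interval. The medians were 1.499 against 1.43, a difference of 0.0681, with an interval that includes 0 (−1.11e-06 to 0.0681). The prediction was therefore not met, although so narrow a miss does not exclude a contribution.

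Replicate 1 also held a larger share of its peaks on gene-dense chromosomes. Over 23 chromosomes, which are not independent samples, the log2 ratio of peak shares had a rho of 0.756 with protein-coding genes per Mb (Pearson's r 0.796, permutation p = 6e-05, adjusted p = 0.00018 over 6 relations), and of 0.697 without chromosomes 19 and 17. If weaker sites of the deeper library were the source, the relation was to vanish among the 10000 strongest peaks of each replicate, and if a bias of the whole library were, fold ratios at shared regions were to follow gene density. The rho values were 0.428 (permutation p = 0.0426, adjusted p = 0.0639) and 0.380 (permutation p = 0.074, adjusted p = 0.0888), between the bounds set beforehand. Pearson's r, for which no bounds were set, was 0.236 and 0.473. The explanations therefore cannot be told apart over 23 chromosomes. Without chromosomes 19 and 17 the rho values were 0.419 and 0.248, so for the fold ratio the place between the bounds (0.3 and 0.5) rests on these chromosomes. The ratio of peak shares also fell with local background in replicate 1 (rho −0.638, permutation p = 0.0016, adjusted p = 0.0032, and −0.547 without chromosomes X and 19), as did the fold ratio (rho −0.808, permutation p = 1e-05, adjusted p = 6e-05, and −0.747 without the same chromosomes), although fold enrichment contains that background.

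The steps of local background along the genome, highest at NKX2-1 and FOXA1, were common to both replicates, whose implied control libraries differed in size. Independent counting noise of each library would not give the rho of 0.939 over 542 bins (permutation p = 0.0001, the smallest possible). That rho restates the common pattern and is not a separate test of it. Gene-dense open chromatin is argued against by a rho of −0.0422 with protein-coding genes per bin. Open chromatin that does not follow gene density was not tested. Copy number segments of this cell line are a candidate explanation: neighbouring bins differed by a mean of 0.168, below each of 1000 shuffles of the bins within chromosomes (0.281 to 0.350), though other properties that vary in long stretches may give the same. Bins with a higher background also held more shared regions (rho 0.559), so peak counts in such bins may be raised. Copy number was not measured here, and the floor hides losses.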
